A study of Oryza sativa with 108 samples.

How the data were processed

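Leaves of the rice cultivar Norin 8 and of osgi, a mutant of the clock gene OsGI, were collected from a paddy field in Japan. Total RNA of both genotypes was labelled with different dyes and hybridised together on 2-colour Agilent oligonucleotide arrays. The series held 108 arrays on 30 slides in 52 groups of sampling time and transplanting date. The 24 h series of Aug 24 to 25 had 78 arrays in 39 groups, with 3 transplantings (May 19, June 19 and July 16), 13 sampling times and 2 replicates. The samples of Aug 10 to 12 (transplanted June 19) had 18 arrays at 9 times. Aug 31 (also June 19) had 4 arrays, 2 at 12:00 and 2 at 18:00. Oct 8 to 9 (transplanted July 31) had 8 arrays at 11:00, 4 on each day.

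Each array file carried 45151 features, of which 1417 were controls. The authors' processed signals are intensities that the scanner software Agilent Feature Extraction 9.5.3.1 had background-subtracted, detrended and dye-normalised, per the submitters' processing notes and the file headers. The mean signals and median background signals are deposited as raw intensity per channel, with no normalization. The deposited quality columns are other values, flags of 0 or 1 for saturation, for outlier pixels and for signal well above background. The deposited log ratio is a log10 ratio of the processed Cy5 signal over the processed Cy3 signal, per the file headers. The series matrix held the same log10 ratios as deposited in the array files, with a largest difference of 4.4e-16. Its column medians lay between -0.005593 and 0, and the values had not been turned for the arrays with the opposite dyes. Its scale, centring and direction could therefore be read from the files, and none of them stayed unknown.

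Per the labels, osgi carried Cy5 in all groups but a few arrays. The dyes were reversed on 2 of the 108 arrays, one at 5:00 on Aug 25 (May 19 transplanting) and one on Oct 8. Their ratios correlated negatively with their sister arrays before turning, with r = -0.76 for the Aug 25 array and -0.68 to -0.40 for the Oct 8 array. The lowest correlation between 2 of the 106 arrays with osgi in Cy5 was -0.34, between an Oct 8 array and an array of 1:00 on Aug 25 (July 16 transplanting), and 2 of their 5565 pairs lay under -0.3. The labelled dyes were kept. Gene-specific dye bias is confounded with genotype on the other 106 arrays.

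Mean signals were corrected with the median background by the normexp method (offset 50) and normalised by loess within arrays in limma 3.58.1 under R 4.3.3, with the data.table package (version 1.17.8). Control features had weight 0. The log2 ratio was turned to osgi over Norin 8. For values within a genotype, the channels were separated after quantile normalization of average intensity between arrays. A probe entered a comparison when it was well above background in either channel on at least 25% of its arrays. Of 43734 non-control features, 1610 matched no RAP locus identifier in the deposited platform annotation. The others held 41908 probes for 29690 loci. Of these loci, 7801 had more than 1 probe, and the probe with the highest mean intensity represented the gene. Of 495 genes with at least 2 called probes, 0 had probes called in both directions. Symbols came from the gene lists, chromosomes can be read from the locus identifiers, and gene coordinates were not given in the sources used here. Where no array of one side of a comparison had signal well above background for a gene, that side was set no lower than the lowest signal found well above background on the array, and the fold is written as "at least".

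Arrays of a time point were averaged before testing, so that time points were the units. In the 24 h series, 39 means were fitted together with transplanting and a cosine and sine of the clock hour (period 24 h) within each transplanting. The genotype comparison was the test of the 24 h mean ratio against 0. Time-of-day effects and rhythms were tested by the moderated F test on both terms. The fitted peak hour and peak-to-trough difference describe a single daily wave. Transplantings were compared on the same means with time point as a block. Samples of Aug 10 to 12 and of Oct 8 to 9 were fitted alone, and the Aug 31 groups within a fit of all 108 arrays. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 1.5-fold. All tests were two-sided. The labels do not say that replicates were separate plants, so the p-values measure only the spread between these samples. Replicate numbers showed no pairing of samples. In the 24 h series the median correlation of replicate differences between groups was 0 over 741 pairs of groups, of which 23.9% exceeded 0.1 (range -0.66 to 0.65), and on Aug 10 to 12 it was -0.04 over 36 pairs (-0.39 to 0.48). In October, differences from the day's mean correlated between days with a median of 0.03 over the 4 pairs of arrays with the same replicate number (-0.26 to 0.13) and -0.01 over the 12 others (-0.25 to 0.36).

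The following gene lists were fixed before the data were examined, as were all comparisons, thresholds, the rule for named genes and the alternatives given in the last paragraph, except that slide as a fixed block was chosen beforehand only for the rhythms and the time-of-day ratio of May 19 plants. Lists by locus were circadian clock, photoreceptors, flowering regulators, chlorophyll breakdown and senescence, panicle and flower markers, and shoot meristem and root markers. Lists by words in the gene description were light-harvesting proteins, photosystem subunits, Calvin cycle, starch and sucrose metabolism, phenylpropanoid and flavonoid synthesis, chlorophyll and carotenoid synthesis, nitrogen assimilation, heat shock proteins, dehydration and cold response, defence proteins, cytosolic ribosomal proteins, plastid-type ribosomal proteins, histones and DNA replication, cell wall growth, and seed storage proteins. List members called were also counted with p adjusted over the list alone, and where a list count stands without that number it was equal. Lists were tested as sets with camera at its preset correlation, with an estimated correlation and with fry, in limma. Camera compares a list with all other genes, whereas fry asks whether its members move at all. The shoot meristem and root list had 1 measured member and was not tested as a set.

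Genes were named by rule. The rule took every clock list member with OsGI at the head, and the 5 largest rises and 5 largest falls among called genes with an informative description that changed the same way in at least 90% of time points or arrays. For rhythms it took the 10 largest peak-to-trough differences. It added up to 3 called members of every other list, or the member with the smallest adjusted p where none was called. Named after their values were seen were Hd1, Ehd1, Hd3a, SE5, DTH8, OsCO3, OsMADS14 and OsMADS15 where the rule did not take them, and the osgi rhythm of a gene that the rule took in Norin 8. Errors given with a log2 ratio are standard errors of the fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

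Alternatives were no background subtraction, the authors' processed signals, other between-array normalization (none for values within a genotype, a scale normalization for ratios), no filter on dim probes, a stricter filter (75% of arrays), the mean over the probes of a gene, the series matrix values, each replicate left out, and a replicate block. Others were slide as a random block (duplicateCorrelation, statmod 1.5.0) or as a fixed block, array-level group means, leaving out the opposite-dye arrays or not turning them, added 12 h harmonics, and time point as a factor. The procedure was tested on simulated data, with changes added in each comparison to 67 genes (1.5-fold), 67 others (2-fold) and 66 more (4-fold). For the osgi rhythms and for July 16 against May 19 in osgi, where a change in Norin 8 and one in the ratio add up, they were 2.25-fold, 4-fold and 16-fold. Of the 1.5-fold changes, 43.3% to 58.2% were recovered for the genotype comparisons of the 24 h series and 38.8% to 47.8% for its time-of-day ratio, but only 8.96% for the time-of-day ratio of Aug 10 to 12 and 10.4% for the October days in the ratio. Of the 2-fold changes, 98.5% to 100% were recovered for the genotype comparisons of the 24 h series, 97.0% for Aug 10 to 12, 94.0% for Oct 8 to 9, 77.6% for either Aug 31 group, and 61.2% for the time-of-day test of Aug 10 to 12. The simulated noise was independent between arrays and had the spread between replicates only. It held no variation by slide, scan day or time point, so recovery in the real data may be lower.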

Results

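The series compared leaves of the rice mutant osgi with leaves of its wild type, the cultivar Norin 8, in the field. OsGI (Os01g0182600) is the rice GIGANTEA gene, a clock gene that also acts in the photoperiodic control of flowering. The data were 2-colour arrays, each with 1 osgi and 1 Norin 8 sample of the same time and transplanting. In the 24 h series of Aug 24 to 25, 78 arrays covered plants transplanted on May 19, June 19 and July 16, sampled at 13 times with 2 replicates. Another 18 arrays came from Aug 10 to 12 (June 19 transplanting, 9 times, 2 replicates), 4 from Aug 31 (June 19, 12:00 and 18:00, 2 replicates) and 8 from Oct 8 to 9 (July 31, 11:00, 4 replicates per day). Transplanting dates were staggered to give plants of different developmental stage on the same sampling date. Signal was well above background for a median of 73.8% of features in the Cy3 channel (66.4% to 79.7%) and 76.9% in the Cy5 channel (70.9% to 81.6%). The median signal was 234 in Cy3 (139 to 365) and 451 in Cy5 (216 to 688), and at most 2 features per array were saturated. The correlation of log2 ratios between the 2 replicates of a group had a median of 0.79, and was lowest, 0.20, at 13:00 on Aug 24 (June 19 transplanting). The number of arrays limits the precision.

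OsGI transcript was lower in osgi than in Norin 8 on every array and with all 4 probes. Its mean log2 ratio by probe was -3.20, -6.24, -2.86 and -5.25. The probe that represents the gene gave a mean of -2.97 for the May 19 transplanting, -2.98 for June 19 and -2.77 for July 16, -2.49 on Aug 10 to 12, -2.97 on Aug 31 and -3.20 on Oct 8 to 9. The osgi signal of that probe was still well above background on every array. The labels do not say where the lesion lies relative to the probes.

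The main question was which genes differ between the genotypes over a whole day. Averaged over the 3 transplantings of the 24 h series, 1805 of 24385 genes differed, 1112 higher and 693 lower in osgi (n = 39 time points). At 2-fold or more, 345 genes were higher and 189 lower. OsGI fell by 2.92 on the log2 scale (± 0.06 SE, adjusted p = 8e-27, 39 of 39 time points). The morning clock gene OsLHY (Os08g0157600) fell by 2.34 (± 0.08, 39 of 39), while OsPRR95 (Os09g0532400) rose by 2.89 ± 0.14 and OsPRR1 (Os02g0618200), the rice TOC1, by 1.81 ± 0.09. The florigen gene Hd3a (Os06g0157700), at -1.33 ± 0.07, was lower in osgi at 39 of 39 time points.

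Of the 14 clock genes, 4 rose and 2 fell. The other rises were OsFKF1 (Os11g0547000), which encodes a blue-light receptor F-box protein, at 2.10 ± 0.15 and OsPRR59 (Os11g0157600) at 0.72 ± 0.05. The 8 clock genes that were not called lay between -0.34 (OsELF3-1, Os06g0142600) and 0.24 (OsELF3-2, Os01g0566100). None of the 6 photoreceptor genes was called, and OsPHYA (Os03g0719800) stood at 0.28. Of 20 flowering regulators, 0 rose and 5 fell, among them OsMADS18 (Os07g0605200) at -1.05 ± 0.08. Tested as a set, the flowering list was lower than other genes for May 19 (adjusted p = 0.03), June 19 (0.00087) and July 16 (0.0036). With an estimated correlation these were adjusted p = 0.51, 0.079 and 0.16, and no list kept a call that way in any comparison tested. The largest rises with a described product included a monosaccharide transporter (Os07g0131600) at 4.68 ± 0.15, a disease-resistance family protein (Os11g0639600; at least 6.71-fold) and an ankyrin-repeat protein (Os05g0124000) at 2.79 ± 0.16. The largest falls included a homeodomain-like protein (Os01g0873000) at -2.68 ± 0.08, an oxygenase of the 2OG-Fe(II) type (Os02g0630300) at -2.20 ± 0.13 and a terpene synthase-like protein (Os03g0348200) at -2.17 ± 0.10.

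Among the metabolic lists, phenylpropanoid and flavonoid synthesis stood out by count, with 20 of 57 genes higher and 2 lower in osgi. Chalcone synthase (Os07g0526400), the entry enzyme of flavonoid synthesis, rose by 1.70 ± 0.18, and the phenylalanine ammonia-lyases Os04g0518400 and Os05g0427400 rose by 1.29 ± 0.16 and 1.15 ± 0.18. Of 17 light-harvesting genes, 3 rose and 1 fell, with opposite changes in Os09g0346500 (1.16 ± 0.13) and Os01g0720500 (-1.95 ± 0.15). Photosystem genes gave 1 rise and 3 falls of 28, with an oxygen-evolving complex protein (Os02g0578400) at 1.06 ± 0.22 and the QB-protein gene Os04g0235200 at -1.02 ± 0.09. In the Calvin cycle list, 0 of 20 rose and 1 fell, a Rubisco small subunit gene (Os12g0274700) at -0.66 ± 0.19. Starch and sucrose metabolism had 1 rise and 3 falls of 32. A beta-amylase gene (Os10g0565200) fell by 2.02 (± 0.12) and granule-bound starch synthase (Os07g0412100) by 0.83 (± 0.09), while an ADP-glucose pyrophosphorylase gene (Os05g0580000) rose by 0.90 ± 0.18. Chlorophyll and carotenoid synthesis had 1 rise and 2 falls of 15, with protochlorophyllide reductase A (Os04g0678700) at 1.07 ± 0.19 and a phytoene synthase family gene (Os12g0626400) at -1.26 ± 0.10. Nitrogen assimilation had 3 rises and 2 falls of 37, with an ammonium transporter (Os05g0468700) at 1.11 ± 0.06 and nitrate reductase (Os08g0468100) at -0.88 ± 0.17. Chlorophyll breakdown had 2 rises and 0 falls of 5, the chlorophyll-degrading SGR (Os09g0532000) at 0.96 ± 0.13 and NYC1 (Os01g0227100) at 0.66 ± 0.10.

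Of 167 defence genes 25 rose and 7 fell, with a thaumatin family gene (Os12g0569500) at 2.04 ± 0.17 and a pathogenesis-related transcription factor (Os09g0287000) at 1.93 ± 0.17. Of 146 heat shock genes 10 rose and 7 fell, including DnaJ family genes Os04g0675400 (2.04 ± 0.12) and Os01g0606900 (1.69 ± 0.19) and a heat shock transcription factor (Os01g0733200, 1.45 ± 0.11). Of 16 dehydration and cold genes, 0 rose and 1 fell (Os01g0314800, -0.65 ± 0.29), a call lost without replicate 1 or 2 (-0.64 and -0.67). Cytosolic ribosomal proteins had 2 rises and 0 falls of 147, with S9 (Os03g0379500) at 1.26 ± 0.05, plastid-type ribosomal proteins 1 rise (Os03g0856500, 0.65 ± 0.13) of 47, histones 1 rise (an H4 gene, Os02g0684500, 0.65 ± 0.08) of 47, and cell wall growth 1 rise (Os08g0434500, 0.72 ± 0.07) of 66. The lists for other tissues had few called genes. Of 8 panicle and flower markers, DL (Os03g0215200) rose by 0.60 ± 0.04 and OsMADS1 (Os03g0215400), a flower MADS-box gene, fell by 1.21 (± 0.08). The only measured meristem and root marker, OSH1 (Os03g0727000), stood at 0.08 and was not called, and 0 of 11 seed storage genes were called. Adjusted over the list alone, the counts of called genes were the same in every list but dehydration, where it was 0. Within the scan days, which hold the times 7:00 to 13:00, 15:00 to 21:00 and 23:00 to 5:00, the mean-of-3 test called 1588, 1851 and 3916 genes. Of the 1805 genes, 92.5%, 93.6% and 99.6% had the same direction within them. With the authors' processed signals 4364 genes were called, as in the series matrix values (4378).

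The same comparison within each transplanting addressed plants of different stage. For May 19, 2256 genes differed (1381 higher, 875 lower), for June 19, 2083 (1255 and 828), and for July 16, 1793 (1107 and 686), with n = 13 time points each. OsGI was at -2.99 ± 0.11, -2.98 ± 0.11 and -2.79 ± 0.11, and OsLHY (Os08g0157600) at -2.30 ± 0.14, -2.53 ± 0.14 and -2.18 ± 0.14. OsPRR95 (Os09g0532400) rose by 2.73 ± 0.24, 3.06 ± 0.24 and 2.88 ± 0.24. With the authors' processed signals the 3 counts were 5168, 4532 and 4091.

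In the earliest plants, transplanted May 19, the largest rises were an RNA-binding-like protein (Os06g0170500) at 6.09 ± 0.12, a protein kinase (Os02g0615800) at 5.64 ± 0.27, the IN2-2 protein (Os04g0338100) at 5.61 ± 0.44 and a Clp ATPase (Os12g0230100) at 4.96 ± 0.38. These SEs rest on a spread estimated over all transplantings. The May 19 arrays varied more widely, with SDs of the ratio over arrays of 1.03, 2.90, 4.08 and 3.52 in the same order. OsMADS15 (Os07g0108900), a MADS-box gene of the floral transition, fell by 1.46 (± 0.17), OsMADS18 (Os07g0605200) by 1.14 (± 0.13) and Hd3a (Os06g0157700) by 1.11 (± 0.12). Of 167 defence genes 34 rose and 11 fell, with a thaumatin gene (Os12g0629700) at 3.03 ± 0.27 and a WRKY gene (Os09g0417800) at 2.69 ± 0.27. Of 57 phenylpropanoid genes 15 rose and 1 fell. As sets, starch and sucrose genes were lower (adjusted p = 0.03; 0.51 with an estimated correlation) and cytosolic ribosomal proteins higher (3.5e-07; 0.75). Light-harvesting genes gave 2 rises and 3 falls of 17 (4 called adjusted over the list alone), and photosystem genes 2 and 5 of 28 (6 alone). SGR (Os09g0532000) rose by 1.67 ± 0.23, the only called chlorophyll breakdown gene of 5 (2 adjusted over the list alone).

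For June 19, the Clp ATPase (Os12g0230100) rose by 8.00 ± 0.38 (256-fold), the monosaccharide transporter (Os07g0131600) by 5.53 ± 0.25 and a thiazole biosynthetic enzyme (Os07g0529600) by 3.72 ± 0.23. A calmodulin-like gene (Os12g0228800) fell by 4.19 (± 0.17) and a Myb gene (Os02g0685200) by 2.73 (± 0.30). Flowering regulators gave 0 rises and 8 falls of 20, with Hd3a (Os06g0157700) at -1.35 ± 0.12. The cytosolic ribosomal proteins had 11 rises and 0 falls of 147, and a median log2 ratio of 0.44. As a set they were higher than other genes (adjusted p = 1.1e-17), with adjusted p = 0.88 with an estimated correlation, and so were plastid-type ones (0.029; 0.95). Phenylpropanoid genes gave 16 rises and 2 falls of 57 (19 called adjusted over the list alone), and light-harvesting genes 5 and 1 of 17.

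For July 16, the latest transplanting of this series, a monosaccharide transporter (Os07g0131600) rose by 5.12 ± 0.25 and a Bowman-Birk inhibitor gene (Os01g0124200) by 3.12 ± 0.23. A methionine aminopeptidase-like gene (Os12g0628500) fell by 5.10 (± 0.34) and a short-chain dehydrogenase (Os12g0609500) was at least 13.3-fold lower. OsMADS14 (Os03g0752800), another gene of the floral transition, fell by 1.49 (± 0.18), Hd3a (Os06g0157700) by 1.52 (± 0.12) and OsMADS1 (Os03g0215400) by 1.82 (± 0.13), and 7 of 20 flowering regulators fell while 0 rose. Cell wall genes gave 12 rises and 0 falls of 66, with a xyloglucan endotransglucosylase (Os06g0697000) at 1.13 ± 0.18. That list was higher as a set (adjusted p = 0.014; adjusted p = 0.80 with an estimated correlation). Of 57 phenylpropanoid genes 18 rose and 1 fell, also higher as a set (adjusted p = 0.011; 0.80 with an estimated correlation), and of 28 photosystem genes 1 rose and 4 fell (4 called adjusted over the list alone), lower as a set (adjusted p = 0.014; 0.80 with an estimated correlation). Cytosolic ribosomal proteins were higher as a set (0.0036; 0.80).

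**Figure D1:**
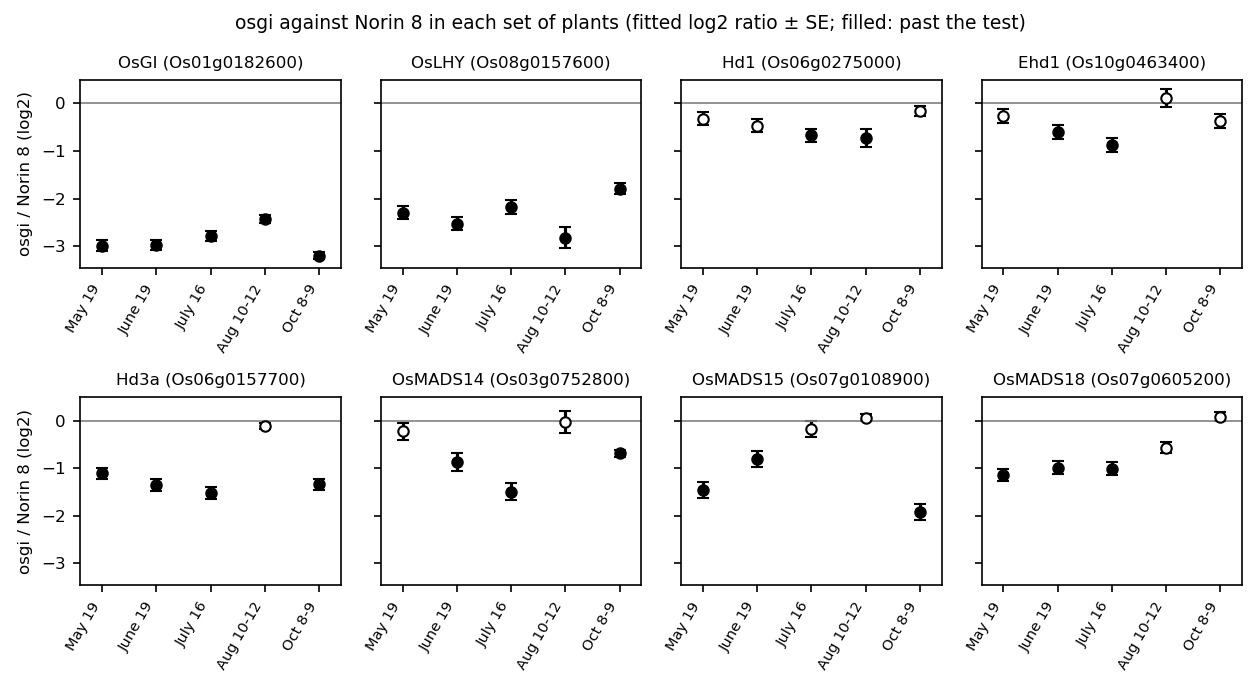
Fitted log2 ratio of osgi over Norin 8 (vertical axis, ± SE) for 8 genes in the 3 transplantings of Aug 24 to 25, on Aug 10 to 12 and on Oct 8 to 9; filled points passed the test. OsGI lies between -3.20 and -2.43 in every set, while Hd3a is at -1.11 to -1.52 in the 24 h series and -0.12 on Aug 10 to 12.

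The next question was whether transcripts cycled over the day. In Norin 8, 12573, 12608 and 13307 genes had a 24 h rhythm in the May 19, June 19 and July 16 plants (51.6%, 51.7% and 54.6% of 24385), with median peak-to-trough folds of 2.28, 2.25 and 2.32. All 6 photoreceptor genes cycled in each transplanting, and 13, 14 and 14 of the 14 clock genes. OsLHY (Os08g0157600) peaked at 6.2 to 6.3 h, OsPRR95 (Os09g0532400) at 11.9 to 12.4 h, OsGI at 15.4 to 15.9 h and OsPCL1 (Os01g0971800), the rice LUX, at 18.3 to 18.9 h. In June 19 plants their peak-to-trough differences were 8.19 ± 0.33, 8.07 ± 0.88, 4.98 ± 0.47 and 7.58 ± 1.04 on the log2 scale (n = 13 time points). Among the largest were a Myb gene (Os02g0685200; peak 3.3 h, 10.63), an isocitrate lyase family gene (Os12g0189300; 7.0 h, 10.59), a fructosyltransferase gene (Os02g0106100; 6.2 h, 8.96) and the plastid sigma factor SIG5 (Os05g0586600; 6.9 h, 8.80). MtN3-type Os01g0700100 varied at least 379-fold. A beta-amylase gene (Os10g0565200) peaked at 0.6 h (8.06), and protochlorophyllide reductase A (Os04g0678700) at 14.6 h (7.50).

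In Norin 8 rhythms were called for 16, 16 and 15 of 17 light-harvesting genes, with median peaks at 11.1, 11.6 and 10.2 h; Os09g0346500 peaked at 11.9 h in June 19 plants. Cytosolic ribosomal proteins cycled in 139, 136 and 132 of 147 genes (139, 136 and 133 adjusted over the list alone), with median peaks at 16.8, 17.5 and 16.6 h, and plastid-type ribosomal proteins in 39, 40 and 42 of 47, at 20.1, 20.2 and 21.1 h. Among the flowering regulators, OsCO3 (Os09g0240200) peaked at 5.9 to 7.0 h, and Hd1 (Os06g0275000), the rice CONSTANS, at 20.9 to 21.5 h, with a June 19 peak-to-trough of 3.25 ± 0.38. Ehd1 (Os10g0463400), which promotes florigen expression, peaked at 3.1 to 3.7 h (3.27 ± 0.27 in June 19 plants). Hd1, Ehd1 and the other flowering genes with a symbol were named here after their values were seen.

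Both genotypes shared 7510, 6970 and 8912 rhythmic genes in the 3 transplantings, against 4451, 4127 and 5781 if independent. Both values of an array are built from its average intensity, so an overlap above independence was partly given by the design. In osgi fewer genes passed the rhythm test, 8632, 7982 and 10593 (35.4%, 32.7% and 43.4%). This order did not hold in every setting: with time point as a factor at array level, 16838, 16595 and 18363 genes were called in Norin 8 and 14503, 15048 and 20441 in osgi, more in osgi for July 16. With slide as a fixed block, where a slide held nearly one time of day, the counts were 1949, 1941 and 2345 in Norin 8 and 1566, 1408 and 1692 in osgi. For some genes the lowest osgi time point of July 16 plants lay far below that of May 19 and June 19 plants. OsCRY1a (Os02g0573200) had 10.42 against 12.88 and 13.15 on the log2 scale, while OsLHY (Os08g0157600) had 7.93 against 7.98 and 7.88. A deviating osgi sample at a single time was not tested for. Fitted peaks came later in osgi. On Aug 10 to 12, with all but 1 array scanned on the same day, the median lag was 0.924 ± 0.138 h. In the 24 h series scan day followed the sampling times, and its part in the lag could not be told apart. Among 5633, 5991 and 5902 genes with clear rhythms in both genotypes, the peak was later by a median of 1.92 ± 0.13, 1.94 ± 0.13 and 1.52 ± 0.20 h (jackknife SE), and later in 91.8%, 90.1% and 84.8% of genes. The peak-to-trough fold in osgi was 79.9%, 77.3% and 84.9% of that in Norin 8, and smaller in 77.1%, 78.4% and 68.0% of genes. OsLHY (Os08g0157600) peaked 2.5 ± 0.2, 2.7 ± 0.2 and 2.5 ± 0.3 h later, OsPCL1 (Os01g0971800) 2.2 ± 0.5, 2.4 ± 0.6 and 2.6 ± 0.5 h later, and OsFKF1 (Os11g0547000) 2.4 ± 0.6, 2.3 ± 0.5 and 3.4 ± 0.7 h later. OsGI itself peaked 0.3 ± 0.2, 0.3 ± 0.1 and 0.4 ± 0.1 h later, and OsPRR37 (Os07g0695100) 0.3 ± 0.1, 0.4 ± 0.1 and 0.1 ± 0.2 h later.

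The daily waves of several clock genes were flatter in osgi. The peak-to-trough difference of OsPRR95 (Os09g0532400) was 2.50 ± 0.48, 2.08 ± 0.42 and 2.00 ± 0.23 in osgi, against 8.30 ± 0.82, 8.07 ± 0.88 and 8.44 ± 0.88 in Norin 8. OsPRR1 (Os02g0618200) had 2.43 ± 0.23, 2.02 ± 0.38 and 2.61 ± 0.22, against 4.82 ± 0.53, 5.48 ± 0.44 and 4.95 ± 0.64. OsPRR59 (Os11g0157600) passed the rhythm test in Norin 8 in each transplanting but not in osgi (adjusted p = 0.60, 0.75 and 0.59), and its ratio changed with the hour (adjusted p = 0.00039, 0.0039 and 2.6e-07). Hd1 (Os06g0275000) peaked 3.8 ± 0.6, 4.2 ± 0.6 and 3.1 ± 0.6 h later in osgi, at 0.7, 1.7 and 0.6 h. Its peak-to-trough was 1.49 ± 0.11, 1.67 ± 0.12 and 2.94 ± 0.48, against 3.40 ± 0.29, 3.25 ± 0.38 and 4.70 ± 0.36 in Norin 8. Ehd1 (Os10g0463400) peaked 2.3 ± 0.6, 1.2 ± 0.9 and 1.8 ± 1.2 h later and OsCO3 (Os09g0240200) 3.0 ± 0.5, 3.2 ± 0.5 and 2.6 ± 0.3 h later. The early light-inducible genes Os07g0178700 and Os01g0246400 had large rhythms in osgi of June 19 plants, peaking at 12.5 and 12.1 h (10.91 and 7.93). The light-harvesting genes cycled in 13, 12 and 12 of 17 (14, 13 and 12 adjusted over the list alone), with median peaks at 13.3, 13.8 and 14.0 h, the cytosolic ribosomal proteins in 40, 16 and 64 of 147 (40, 15 and 64 alone), and the plastid-type ones in 15, 8 and 17 of 47 (14, 8 and 16 alone).

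**Figure D2:**
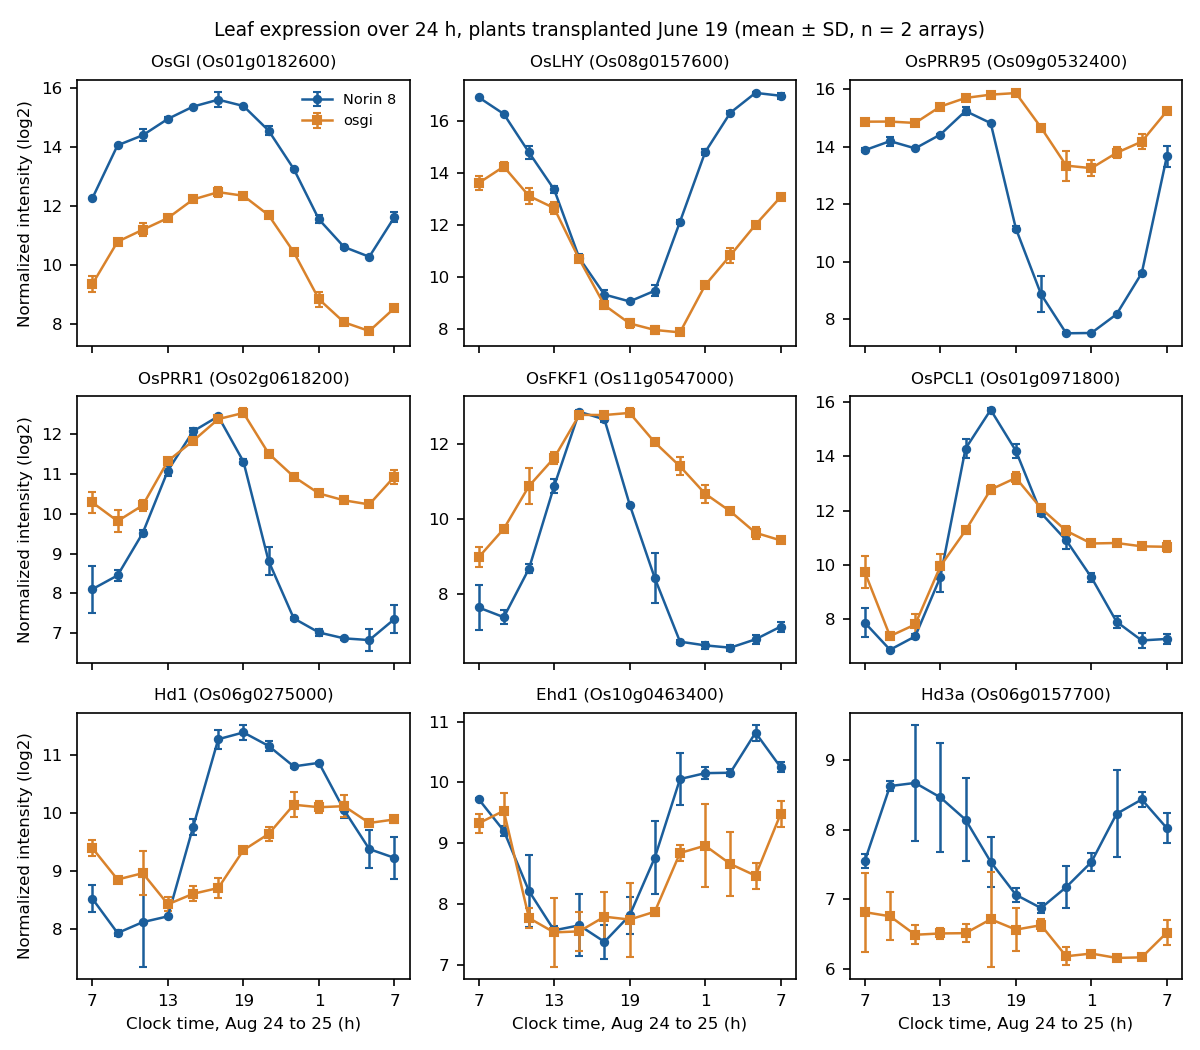
Normalized log2 intensity (vertical axis, mean ± SD of 2 arrays) over the clock hour (horizontal axis) for 9 clock and flowering genes in Norin 8 and osgi plants transplanted June 19. OsGI is lower in osgi at all 13 times, OsLHY peaks at 9.0 h in osgi and 6.3 h in Norin 8, and the wave of OsPRR95 is flatter in osgi.

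**Figure D3:**
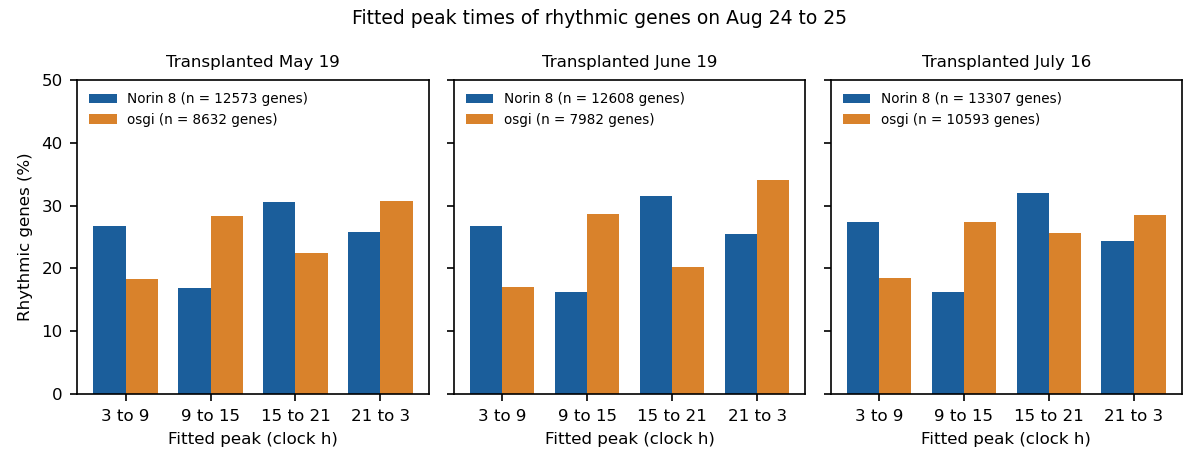
Share of the rhythmic genes (vertical axis, percent) with a fitted peak in each of 4 windows of the day (horizontal axis, h), for both genotypes and 3 transplantings. In Norin 8 26.8%, 26.8% and 27.3% of genes peak between 3 and 9 h, in osgi 18.4%, 17.0% and 18.5%, and the share between 9 and 15 h is 16.2% to 16.9% in Norin 8 and 27.3% to 28.7% in osgi.

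The ratio itself changed with the time of day, a direct test of a different daily course, for 6637, 6286 and 7165 genes. OsGI did so in May 19 (peak-to-trough of the ratio 1.32, adjusted p = 0.0042) and July 16 plants (1.37, 0.003), and stood at 0.68 in June 19 plants (adjusted p = 0.2, not called). Of 14 clock genes 10, 8 and 12 were called, led by OsPRR95 (Os09g0532400; 6.18, 6.24 and 7.27), OsPCL1 (Os01g0971800; 4.75, 5.14 and 5.03) and OsLHY (Os08g0157600; 4.87, 5.26 and 4.50). Large changes were also seen in a Myb gene (Os04g0583900; 8.58, 8.16 and 7.42), protochlorophyllide reductase A (Os04g0678700; 6.96, 7.52 and 7.75), the terpene synthase-like Os08g0139700 (6.56, 6.90 and 6.81) and the beta-amylase gene Os10g0565200 (6.39, 5.81 and 5.80). Hd1 (Os06g0275000) gave 2.89, 2.90 and 3.44. The clock genes OsELF3-1 (Os06g0142600) and OsELF4a (Os11g0621500) were called in July 16 plants only. Their osgi waves there were poorly fitted, with peak-to-trough differences of 0.61 ± 0.53 and 0.63 ± 0.41. The lowest osgi levels, 10.21 and 10.13, lay below those of May 19 (11.28 and 11.63) and June 19 plants (11.43 and 11.84). Whether a single time point carried these 2 calls was not tested. Light-harvesting genes were called in 12, 12 and 14 of 17, flowering regulators in 12, 11 and 10 of 20 and starch and sucrose genes in 14, 15 and 22 of 32 (14, 16 and 22 adjusted over the list alone). Of 147 cytosolic ribosomal proteins 132, 136 and 22 were called (134, 137 and 3 adjusted over the list alone). Sampling times were scanned together in groups. Inside those groups (7:00 to 13:00, 15:00 to 21:00, 23:00 to 5:00) time points differed for 8216, 6447 and 5412 genes in Norin 8. The ratio gave 4487, 2816 and 130. The osgi counts were 6113 (7:00 to 13:00) and 5284 (15:00 to 21:00), but fell below 130 for 23:00 to 5:00, against 5412 in Norin 8. The cause of this low osgi count, and its bearing on the osgi rhythm and ratio counts, was not tested. With slide as a fixed block the ratio test called 134, 51 and 36 genes; a slide held nearly one time of day.

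Samples of Aug 10 to 12, from June 19 plants about 2 weeks earlier, gave 1599 genes of 24270, 1119 higher and 480 lower in osgi (n = 9 time points). OsGI fell by 2.43 (± 0.09) and OsLHY (Os08g0157600) by 2.82 (± 0.22), each at 9 of 9 time points. OsFKF1 (Os11g0547000) rose by 2.62 ± 0.38, OsPRR95 (Os09g0532400) by 2.51 ± 0.41 and OsPRR1 (Os02g0618200) by 1.79 ± 0.16. Hd3a (Os06g0157700) stood at -0.12 ± 0.06 and was not called. SE5 (Os06g0603000), needed for phytochrome chromophore synthesis, fell by 0.78 (± 0.06) and Hd1 (Os06g0275000) by 0.73 (± 0.18), and of 20 flowering regulators 0 rose and 3 fell. The Clp ATPase (Os12g0230100) rose by 7.98 ± 0.07 (252-fold), the monosaccharide transporter (Os07g0131600) by 5.60 ± 0.06 and a Bowman-Birk inhibitor (Os01g0124200) by 4.17 ± 0.39, while the calmodulin-like Os12g0228800 fell by 3.59 (± 0.16) and the Myb gene Os04g0583900 by 2.91 (± 0.21).

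Plastid-type ribosomal proteins rose in 9 of 47 genes on Aug 10 to 12 and fell in 0, among them L4 (Os03g0265400) at 0.89 ± 0.05. As a set they were higher (adjusted p = 1.8e-09; adjusted p = 0.66 with an estimated correlation), as were cytosolic ones (9.1e-06; 0.82). Light-harvesting genes rose in 6 of 17 and fell in 0, with Os09g0346500 at 1.18 ± 0.14 and Os03g0592500 at 1.09 ± 0.11 (as a set adjusted p = 0.017; 0.82 with an estimated correlation). Histones rose in 5 of 48, with H2A (Os03g0279200) at 0.93 ± 0.18 (as a set adjusted p = 0.0039; 0.82 with an estimated correlation). Phenylpropanoid genes gave 8 rises and 1 fall of 57, with the ammonia-lyases Os12g0520200 at 1.92 ± 0.18 and Os04g0518400 at 1.73 ± 0.17. Defence genes gave 17 rises and 2 falls of 160 (16 called adjusted over the list alone), and heat shock genes 10 and 5 of 142, with DnaJ gene Os04g0675400 at 3.13 ± 0.40. The ratio changed with time of day for 2561 genes, including 6 of 14 clock genes (7 adjusted over the list alone). The largest was a CONSTANS-type zinc finger gene (Os06g0298200; 7.14), followed by the Myb gene Os04g0583900 (7.02), and OsGI was at 1.21 (adjusted p = 0.042). All but 1 of these arrays were scanned on the same day. Without replicate 1 the time-of-day count was 1098 and OsGI (1.14) was not called, while the count was 6135 with a replicate block, 5973 with slide as a random block and 10706 with time point as a factor. With the authors' processed signals 3642 genes differed in the day average.

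On Aug 31, single times of day were compared in June 19 plants, with 2 arrays each. At 12:00, 2926 of 22802 genes differed (1865 higher, 1061 lower), and at 18:00, 2640 of 23093 (1523 and 1117). OsGI fell by 3.11 (± 0.19) at 12:00 and by 2.82 (± 0.19) at 18:00. OsLHY (Os08g0157600) fell by 2.01 (± 0.18) and 1.11 (± 0.18). At 18:00 OsPCL1 (Os01g0971800) fell by 2.62 (± 0.37), OsELF3-2 (Os01g0566100) by 1.42 (± 0.22) and Hd1 (Os06g0275000) by 1.93 (± 0.23, adjusted p = 2.8e-09).

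At 12:00 the clock list gave 1 rise and 5 falls of 14. OsPRR37 (Os07g0695100), OsPRR59 (Os11g0157600) and OsPRR73 (Os03g0284100) fell by 1.04 (± 0.17), 0.91 (± 0.15) and 0.89 (± 0.18), and OsPCL1 (Os01g0971800) rose by 1.28 ± 0.37, a call lost without replicate 2 (0.02). The Clp ATPase (Os12g0230100) rose by 7.43 ± 1.38 and the monosaccharide transporter (Os07g0131600) by 5.62 ± 0.87. Plastid-type ribosomal proteins gave 24 rises and 1 fall of 47, with L18 (Os03g0828100) at 2.44 ± 0.27 and L13 (Os01g0749200) at 2.16 ± 0.22. Calvin cycle genes gave 6 rises and 1 fall, including Rubisco genes Os06g0598500 (1.48 ± 0.26) and Os12g0291100 (1.40 ± 0.22). Phenylpropanoid genes gave 15 rises and 0 falls of 59, with cinnamyl-alcohol dehydrogenase (Os02g0187800) at 2.87 ± 0.55 and ammonia-lyase Os05g0427400 at 2.79 ± 0.58. A light-harvesting gene (Os09g0439500) rose by 2.33 ± 0.26 and granule-bound starch synthase (Os07g0412100) fell by 2.21 (± 0.36). Of the 2 chlorophyll breakdown genes that fell, PAO (Os03g0146400; -0.78 ± 0.24) stood at 0.06 without replicate 2 and NYC1 (Os01g0227100; -0.74) was not called without it (-0.57).

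At 18:00 the clock list gave 0 rises and 6 falls of 14. The Myb gene Os04g0583900 was at least 39.1-fold lower, the CONSTANS-type genes Os06g0298200 and Os02g0724000 fell by 5.28 (± 0.29) and 3.77 (± 0.26), and the beta-amylase gene Os10g0565200 by 4.58 (± 0.35). A light-harvesting gene (Os09g0346500) rose by 1.38 ± 0.30, an H2B gene (Os01g0152900) by 1.06 ± 0.17 and a PR1-type gene (Os07g0125000) by 1.77 ± 0.19, while NADH-dependent glutamate synthase (Os01g0681900) fell by 1.81 (± 0.28) and DnaJ gene Os04g0675400 by 1.92 (± 0.41). Histones gave 8 rises and 0 falls of 46 (11 called adjusted over the list alone), and phenylpropanoid genes 10 and 0 of 55 (5 alone). Both groups lay on 1 slide. With the authors' processed signals 52.4% of the called genes at 12:00 were higher in osgi, against 63.7% here, and with other between-array normalization the counts were 1644 and 1360 and OsGI (Os01g0182600; -2.81 and -2.55, adjusted p = 0.14 and 0.19) no longer passed.

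In October, plants transplanted on July 31 were compared at 11:00. Over both days 2785 of 23956 genes differed, 1495 higher and 1290 lower in osgi (n = 8 arrays). OsGI fell by 3.20 (± 0.07), OsLHY (Os08g0157600) by 1.79 (± 0.11), OsMADS15 (Os07g0108900) by 1.92 (± 0.17) and OsMADS1 (Os03g0215400) by 2.17 (± 0.10) and the senescence regulator OsNAP (Os03g0327800) stood at -2.63 ± 0.15 (called). Hd3a (Os06g0157700) was at least 2.52-fold lower. The pathogenesis-related gene PRB1-2 (Os01g0382400) rose by 5.46 ± 0.21, the chitinase genes Os04g0493400 and Os04g0494100 by 5.40 ± 0.23 and 4.28 ± 0.26, and the disease-resistance family gene Os11g0639600 was at least 24.7-fold higher.

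Plastid-type ribosomal proteins rose in 22 of 47 genes in October and fell in 0, with L18 (Os03g0828100) at 1.66 ± 0.16 and L6 (Os03g0751400) at 1.66 ± 0.21 (as a set adjusted p = 6.7e-14; 0.40 with an estimated correlation). Cytosolic ribosomal proteins rose in 10 of 146, with S9 (Os03g0379500) at 2.02 ± 0.16 (as a set adjusted p = 1.1e-11; 0.58 with an estimated correlation). Photosystem genes gave 13 rises and 4 falls of 28 (as a set adjusted p = 0.018; 0.58 with an estimated correlation), from 2.88 ± 0.22 (Os02g0578400) to -2.70 ± 0.47 (Os07g0147500, a photosystem II 10 kDa protein). Calvin cycle genes gave 8 rises and 0 falls of 20 (as a set adjusted p = 0.0033; 0.40 with an estimated correlation), with a Rubisco small subunit gene (Os12g0274700) at 2.10 ± 0.21. Starch and sucrose genes gave 8 rises and 2 falls of 33, with a starch synthase (Os06g0229800) at 2.47 ± 0.22 and sucrose synthase 2 (Os03g0401300) at 2.45 ± 0.21. Phenylpropanoid genes gave 15 and 3 of 61, with ammonia-lyase Os12g0520200 at 2.32 ± 0.17, and cell wall genes 16 and 4 of 66, with cellulose synthase 7 (Os07g0424400) at 1.88 ± 0.17. As sets these were higher (adjusted p = 0.0028 and 0.0074; 0.58 and 0.40 with an estimated correlation). Flowering regulators gave 1 rise and 6 falls of 20 and histones 0 and 7 of 45, the former lower as a set (adjusted p = 0.0074; 0.40 with an estimated correlation), the latter too (0.029; 0.58), as was the clock list (0.011; 0.58). With the authors' processed signals 4732 genes were called, and with other between-array normalization 1851.

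The genotype ratio was also compared between Oct 9 and Oct 8. Nicotianamine synthase (Os07g0689600), an enzyme of iron chelator synthesis, fell by 4.88 (± 0.22, adjusted p = 0.00017) in the ratio, an actin-depolymerizing factor (Os12g0628100) by 4.12 (± 0.94) and OsLHY (Os08g0157600) by 1.31 (± 0.21). A germin-like gene (Os08g0231400) rose at least 10.8-fold and sucrose synthase 2 (Os03g0401300) by 3.14 ± 0.42. OsGI was at -0.10 ± 0.13 and was not called. In all 968 genes were called, 421 higher and 547 lower (n = 4 arrays per day). Of 14 clock genes 0 rose and 1 fell (9 adjusted over the list alone), of 20 flowering regulators 0 and 2 (6 alone) and of 47 plastid-type ribosomal proteins 2 and 3 (26 alone). The count was 1 without replicate 1, 369 without 2, 6 without 3, 1003 without 4, 39 without the opposite-dye array and 0 with a replicate block, and of the genes named only Os07g0689600 kept its call without any single replicate. Over the same settings OsLHY lay between -1.35 and -1.23 where its call was lost, Os12g0628100 between -4.15 and -3.64, Os08g0231400 was fitted at 3.43 and 3.75 and Os03g0401300 at 2.97 and 3.15. Day and slide cannot be told apart in October.

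Between the same days Norin 8 differed in 3960 genes, 2124 higher and 1836 lower on Oct 9. Of 14 clock genes 10 rose, among them OsPCL1 (Os01g0971800) by 2.38 ± 0.33, OsFKF1 (Os11g0547000) by 1.53 ± 0.21 and OsLHY (Os08g0157600) by 0.98 ± 0.17. OsGI rose by 0.59 ± 0.12, and was not called without replicate 1 or 2 (0.50). A myo-inositol phosphate synthase gene (Os03g0192700) rose by 3.68 ± 0.27 and a dehydrin (Os11g0454300) by 3.63 ± 0.57, while the photosystem II 10 kDa gene (Os07g0147500) fell by 5.54 (± 0.93), a bHLH gene (Os04g0301500) by 5.20 (± 0.65) and a small heat shock protein (Os02g0758000) by 3.41 (± 0.55). Heat shock genes gave 15 rises and 21 falls (38 called adjusted over the list alone), cytosolic ribosomal proteins 0 and 34 (41 alone) and flowering regulators 7 and 1. Without replicate 1, 2580 genes were called.

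The last question was how plants of different developmental stage differed on Aug 24 to 25. In Norin 8, 3162 genes differed between July 16 and May 19 plants, 1540 higher and 1622 lower in the later transplanted July 16 plants (n = 13 time points). The floral transition genes OsMADS14 (Os03g0752800) and OsMADS15 (Os07g0108900) fell by 4.36 (± 0.20) and 4.06 (± 0.19), and the senescence regulator OsNAP (Os03g0327800) by 1.91 (± 0.21). OsMADS50 (Os03g0122600), the rice SOC1, rose by 1.51 ± 0.10. OsGI stood at -0.06 ± 0.09, and 0 of 14 clock genes and 0 of 6 photoreceptor genes were called. An RNase T2 gene (Os09g0537700) rose by 6.33 ± 0.24, a phosphoethanolamine methyltransferase gene (Os05g0548900) by 5.06 ± 0.21 and a branched-chain aminotransferase gene (Os01g0238500) by 4.41 ± 0.27, while an SP3D-type gene (Os01g0218500) fell by 4.54 (± 0.20).

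Cell wall genes gave 13 rises and 2 falls of 66 in this comparison, with the expansins Os10g0555900 (3.09 ± 0.29) and Os01g0823100 (2.80 ± 0.26). As a set they were higher (adjusted p = 0.0017; 0.37 with an estimated correlation). So were plastid-type ribosomal proteins (6 rises, 0 falls of 47; adjusted p = 3.4e-05; 0.37 with an estimated correlation), cytosolic ribosomal proteins (3 and 0 of 147; 0.00016; 0.76 estimated), starch and sucrose genes (6 and 0 of 32; 0.0055; 0.15 estimated) and chlorophyll and carotenoid synthesis (5 and 1 of 15; 0.0055; 0.37 estimated). Defence genes gave 18 rises and 38 falls of 167, with a pathogenesis-related transcription factor (Os05g0549800) at -2.84 ± 0.14 and a WRKY gene (Os07g0111400) at -2.29 ± 0.18. Phenylpropanoid genes went both ways, 11 rises and 19 falls of 57, from ammonia-lyase Os12g0520200 at 3.01 ± 0.18 to cinnamyl-alcohol dehydrogenase Os02g0187800 at -2.49 ± 0.20. Nitrogen assimilation gave 2 and 7 of 37, with ammonium transporter Os03g0838400 at -2.49 ± 0.21 and glutamine synthetase Os03g0223400 at 1.41 ± 0.12. The flowering list gave 3 and 2 of 20, with a median of 0.04, a mean of -0.22 and a set test pointing up (adjusted p = 0.77). Within the scan days 2660, 3027 and 3914 genes were called. With other between-array normalization, here none, 6882 genes were called, of which 7.61% were higher against 48.7% here, and the median of all genes shifted by -0.41. The authors' processed signals gave 6440.

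June 19 plants differed from May 19 plants in 669 genes in Norin 8, 278 higher and 391 lower. OsMADS15 (Os07g0108900) fell by 2.93 (± 0.19) and OsMADS14 (Os03g0752800) by 1.68 (± 0.20), while a MADS-box gene (Os03g0186600) rose by 1.97 ± 0.10. OsGI stood at 0.15 and was not called. Defence genes gave 3 rises and 22 falls of 167 and phenylpropanoid genes 1 and 13 of 57, with cinnamyl-alcohol dehydrogenase Os02g0187800 at -1.97 ± 0.20 and ammonia-lyase Os05g0427400 at -1.74 ± 0.24. By scan day 125 (78 higher, 47 lower), 462 (271 and 191) and 1193 (469 and 724) genes were called, so the balance of directions differed between scan days. With the authors' processed signals 1736 were called.

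In osgi the July 16 and May 19 plants differed in 4747 genes, 2337 higher and 2410 lower. The RNase T2 gene (Os09g0537700) rose by 9.17 ± 0.32 (576-fold), the expansin Os01g0823100 was at least 16.1-fold higher, and the RNA-binding-like Os06g0170500 at least 121-fold lower. OsMADS14 (Os03g0752800) fell by 5.59 (± 0.22) and OsMADS15 (Os07g0108900) by 2.81 (± 0.21), and DTH8 (Os08g0174500), a regulator of heading date, rose by 1.83 ± 0.21. OsGI stood at 0.14 and was not called; 2 of 14 clock genes fell, OsPCL1 (Os01g0971800; -0.71) and OsELF3-2 (Os01g0566100; -0.62). Cell wall genes gave 21 rises and 4 falls of 66, starch and sucrose genes 11 and 1 of 32, and chlorophyll breakdown genes 0 and 4 of 5, with OsNAP (Os03g0327800) at -2.67 ± 0.38. Within the scan days 4648, 5479 and 2991 genes were called, and with other between-array normalization (none) 8164 (median shift -0.40), of which 11.3% were higher against 49.2% here. The authors' processed signals gave 8315. Between June 19 and May 19, 959 genes differed in osgi, 407 higher and 552 lower, with OsMADS14 at -2.33 ± 0.22, OsMADS15 at -2.29 ± 0.21, OsMADS50 (Os03g0122600) at 1.06 ± 0.12 and OsGI at 0.15 (not called). Defence genes gave 6 and 18 of 167 (27 called adjusted over the list alone). Within the scan days 982, 1373 and 54 were called, and with the authors' processed signals 2087 (1091 higher, 996 lower).

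The ratio tested whether the genotype difference changed between July 16 and May 19 plants, and did so for 909 genes, 418 higher and 491 lower, of which 298 at 2-fold or more. OsMADS15 (Os07g0108900) rose by 1.25 ± 0.25 in the ratio, being less reduced in osgi in the July 16 plants, and OsMADS1 (Os03g0215400) fell by 1.41 (± 0.20). OsMADS14 (Os03g0752800; -1.23 ± 0.26) was not called without replicate 1 (-1.19). OsGI was at 0.20 ± 0.11 and was not called. Changes of the ratio included Os11g0229500 at 3.61 ± 0.37, the Bowman-Birk inhibitor Os01g0124000 at 2.87 ± 0.35 and the Clp ATPase Os12g0230100 at -5.06 ± 0.56. For 32 of the called genes the change had no measurable size, as signal was not well above background on one side. Among them were the RNA-binding-like Os06g0170500 (neither genotype in July 16 plants), the kinase Os02g0615800 and the IN2-2 gene Os04g0338100 (Norin 8 in July 16 plants) and the TT12-type transporter Os03g0571700 (neither genotype in May 19 plants). Cell wall genes gave 11 rises and 2 falls of 66 (15 called adjusted over the list alone), defence genes 15 and 8 of 167 (27 alone) and flowering regulators 1 and 2 of 20 (4 alone). By scan day the counts were 1035, 1007 and 46. With slide as a fixed block, an alternative chosen after seeing the data, 1642 were called (878 higher, 764 lower), and with the authors' processed signals 2139.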

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

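The tests of dye bias, of a compressed Cy5 channel, of slide and of chromosome segments were chosen after the results were seen.

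The genotype difference itself differed between July 16 and May 19 plants for 909 genes, by a test of the ratio between transplantings. No split other than the real one among 100 regroupings of the transplantings within time points called as many (highest other 0), which argues against chance. The called genes named above include changes of 3.61 (Os11g0229500), 2.87 (Os01g0124000), 2.84 (Os09g0537700, RNase T2) and 2.56 (Os01g0382400, PRB1-2) upward and -5.06 (Os12g0230100, Clp ATPase) downward. The fitted values 2.33 (Os03g0571700), -5.98 (Os06g0170500), -5.65 (Os02g0615800), -5.55 (Os04g0338100) and -3.21 (Os02g0615500, kinase) rest on a side not well above background and give no measured size. Among genes of the lists, the test of the difference gave OsMADS15 (Os07g0108900) 1.25, OsMADS14 (Os03g0752800) -1.23, Ehd1 (Os10g0463400) -0.62, OsMADS1 (Os03g0215400) -1.41, the photosystem II gene Os07g0147500 -2.09, the DnaJ gene Os01g0606900 1.61 and the expansin Os01g0823100 a fitted 1.25 (at least 2.32-fold). Without replicate 1 the calls of OsMADS14 (-1.19), Ehd1 (-0.66) and Os01g0823100 (1.35) were lost, and the last also without replicate 2 (1.14).

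Of these genes, 43 had a fitted change of the ratio of 4-fold or more between the transplantings, 16 upward and 27 downward, of which 6 give no measured size. Slide as the cause was argued against by a fit with slide as a fixed block, in which 93.0% (40) kept call and direction. A fault of single probes was argued against by the other probes of 10 of these genes, of which 23 of 23 (100%) moved the same way. A candidate explanation that stays open is that osgi plants carried different chromosome segments. Of the 43 genes, 12 had another such gene within 5 places in locus order, against a highest value of 8 in 10000 random draws. Without those of no measured size it was 10 of 37 (highest 8). Of 166 genes with a 4-fold change in Norin 8, 19 had one (highest of 1000 draws 28). It is a hypothesis found in the same data, and some of these neighbours are relatives of each other. A difference in stage, which the design names, was not excluded for the genes as a whole. For some genes it is argued against as the sole cause. Their ratio switched between arrays of the later October day, which share hour and transplanting. Os12g0221600 read 3.22, -0.02, 2.9 and 3.71 there, and Os12g0230100 7.88, -0.13, 7.91 and 7.82. Os12g0609500 read -5.06, -5.16, 0.13 and -3.76, and Os12g0628500 -5.97, -5.79, 0.06 and -5.84. Others, such as Os12g0516000 (-4, -4.56, -4.07 and -3.74), did not switch.

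The genotype ratio differed between Oct 9 and Oct 8 for 968 genes by a test of the difference. Of 35 splits of the 8 arrays, 1, the real one, gave as many (highest other 0), but day and slide cannot be told apart. The named genes were Os08g0231400 (germin-like, a fitted 3.48, at least 10.8-fold), Os03g0401300 (3.14, sucrose synthase 2), Os02g0819400 (2.47, globin-like), Os07g0645000 (2.25), Os01g0192000 (2.24), Os07g0689600 (-4.88, nicotianamine synthase), Os12g0628100 (-4.12), Os06g0141200 (-3.70), Os01g0179600 (-3.58) and Os12g0231000 (-3.56). From the lists came OsLHY (Os08g0157600, -1.31), OsDof12 (Os03g0169600, -1.83), DTH8 (Os08g0174500, -1.65), Os01g0720500 (-3.11, light-harvesting), OsMADS1 (Os03g0215400, -1.37) and Os08g0500700 (1.76, HSP82). Of these, only Os07g0689600 kept its call without each single replicate, and the count was 1, 369, 6 and 1003 without replicates 1, 2, 3 and 4.

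Single arrays stood apart from the 3 others of their day, relative to the range, in 4 of 134 groups examined. Chance alone gives about 1 in 20, so for these groups this is no more than chance gives. The groups held only genes picked for the October comparisons. Not among them were Os12g0230100 (7.88, -0.13, 7.91 and 7.82 on Oct 9), Os12g0628500 (-5.97, -5.79, 0.06 and -5.84) and Os09g0467700 (4.95, 5.15, 0.19 and 5.01). Each had 1 array far from the 3 others, so the count does not bear on such genes. The gap to the nearest array took a share of 0.8887 of the range for the ratio of Os01g0192000 on Oct 9 (replicate 3). It took 0.8291 for Os01g0382400 on Oct 9 (replicate 4), whose 4 arrays all lay between 5.05 and 5.44. The share was 0.8936 for OsMADS15 (Os07g0108900) on Oct 8 (replicate 1) and 0.8611 for Os07g0424400 on Oct 8 (replicate 4, the array with opposite dyes).

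The rhythms of osgi were later and shallower than those of Norin 8, as given above. A Cy5 channel compressed before normalization, as the cause of the shallower rhythms, was argued against. Over the genes rhythmic in both genotypes (10938), the SD of log2 signal before normalization was 1.06 times as large in Cy5 as in Cy3. The means of 78 arrays were 2.40 against 2.27 (SE of the ratio 0.00378, lowest array 0.984), where compression would give less than 1. The rhythms were fitted on normalised values, whose range by channel was not tested, so a compression arising there was not excluded. In the 24 h series, where scan day followed the sampling times, its part in the later peaks could not be told apart. On Aug 10 to 12, with all but 1 array scanned on the same day, the median peak difference was 0.924 ± 0.138 h, 75.9% of 6968 genes peaked later in osgi, and the peak-to-trough fold was 76.6% of that in Norin 8. That lag lay between the bounds set beforehand for and against scan day, so the test did not decide by its own rule. A lag several times its error, with nearly all arrays on 1 scan day, argues against scan day as the whole cause. It was smaller than in the 24 h series, so part of the latter may follow the scan days.

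The number of genes that differ between the genotypes was weighed against dye bias, since osgi carried Cy5 on all but 2 arrays. Bias between the channels as the whole cause was argued against by the opposite-dye arrays. On these, after turning, 90.9% (Aug 25) and 89.5% (Oct 8) of the genes called without them kept their sign. The changes were smaller there, with slopes of 0.62 and 0.80 on the values fitted from all arrays but these. A gene-specific dye effect may still shift single ratios.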

How the results depend on the processing

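Of 364 counts of called genes under the alternatives, 306 stayed within 1.5 times the reported count and 58 moved further. All counts stayed within that range with no background subtraction, no filter on dim probes, a filter at 75% of arrays, the mean over the probes of a gene, 24 h and 12 h harmonics, and array-level group means. So they did with scan day as a fixed block and with the 2 time points of low replicate correlation left out, both chosen after seeing the data. The named genes gave 26484 values under the alternatives, of which 24713 kept direction and call, 1583 lost the call, 187 gained it and 1 reversed. The reversal was PAO (Os03g0146400) at 12:00 on Aug 31, at 0.06 without replicate 2 and -1.63 without replicate 1, against -0.78. Slide as a fixed block lost 556 of 1059 of the named values, without replicate 1 lost 185 of 1815 and other between-array normalization 176 of 1815.

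The cause was not tested for the moved counts below unless the construction shows it. With the processed signals of the scanner software, the counts for osgi against Norin 8 were 5168 (May 19), 4532 (June 19), 4091 (July 16), 4364 (mean of 3), 3642 (Aug 10 to 12), 4936 (Aug 31, 12:00), 4288 (18:00) and 4732 (Oct 8 to 9). For the transplantings they were 6440 and 1736 in Norin 8 (July 16 and June 19 against May 19), 8315 and 2087 in osgi and 2139 in the ratio, and 266 for the October days in the ratio. The series matrix values, from the same signals, gave 5155, 4540, 4089, 4378, 3653, 4935, 4296, 4733, 2099 and 257 for those that use ratios. Other between-array normalization gave 6882 (July 16 against May 19 in Norin 8), 8164 (in osgi), 1644 and 1360 (Aug 31) and 1851 (Oct 8 to 9).

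A replicate block gave 6135 for the time-of-day ratio of Aug 10 to 12 and 0 for the October days in the ratio, although replicate numbers showed no pairing. Slide as a random block gave 5973 for the former. The October days in the ratio gave 39 without the opposite-dye array, and not turning the opposite-dye arrays gave 737 for Oct 8 to 9. With time point as a factor at array level, which also tests courses other than a single wave and counts replicates as units, the time-of-day ratio gave 12402, 12522 and 17949 genes, the osgi rhythm 14503, 15048 and 20441 (Norin 8 16838, 16595 and 18363), and Aug 10 to 12 10706. With slide as a fixed block, a slide holding nearly one time of day and so by construction taking up most variation with time, the May 19 counts were 1949 (Norin 8 rhythm), 1566 (osgi rhythm) and 134 (time-of-day ratio). The same setting, chosen after seeing the data for the other transplantings, gave 1941 and 2345 (Norin 8 rhythm), 1408 and 1692 (osgi rhythm), 51 and 36 (time-of-day ratio), and 1642 for July 16 against May 19 in the ratio. Of the gene list tests 29 were called, 0 with an estimated correlation and 66 with fry, which asks another question.

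With each replicate left out, the counts ranged from 2205 to 2296, 1879 to 2331, 1699 to 1918 and 1816 to 1847 for osgi against Norin 8 (May 19, June 19, July 16, mean of 3), and from 5162 to 6417, 4850 to 6539 and 6384 to 6404 for the time-of-day ratio. Norin 8 rhythms ranged from 12316 to 12426, 11942 to 12875 and 12589 to 14187, and osgi rhythms from 7913 to 8412, 7450 to 7483 and 9836 to 10698. Transplantings ranged from 3182 to 3263 and 624 to 678 in Norin 8, 4635 to 4859 and 703 to 1053 in osgi, and 670 to 735 in the ratio. Aug 10 to 12 ranged from 1258 to 1901 (time of day 1098 to 2058), Aug 31 from 2480 to 3449 and 1999 to 2477, Oct 8 to 9 from 2243 to 2883, and the October days from 1 to 1003 (ratio) and 2580 to 3752 (Norin 8). Where this left 1 array in a group, it was assumed to vary like the other groups.

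Not run were 12 h harmonics for Aug 10 to 12, whose 4 clock hours cannot carry them, and slide as a random block in October, where day and slide coincide. A median of 73.8% of Cy3 and 76.9% of Cy5 features lay well above background, and genes above it in neither channel on 25% of arrays were not tested.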

Other observations

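The counts of other splits below were tests chosen before the results were seen; the genes given with ratios by set were chosen after their values were seen, as was the look at which plants the splits exchanged.

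Rhythms in metabolic lists are given here for June 19 plants (n = 13 time points), in which 51.7% of all genes were called in Norin 8 and 32.7% in osgi. They were called for 24 of 32 starch and sucrose genes in Norin 8, with a median peak at 6.7 h, and for 20 in osgi, at 9.5 h (24 and 20 adjusted over the list alone). Nitrogen assimilation had 25 of 37 rhythmic genes in Norin 8, at 9.2 h, and 19 in osgi, at 13.1 h (25 and 19 alone), and phenylpropanoid and flavonoid synthesis 36 of 57, at 8.8 h, and 25, at 12.2 h (36 and 25 alone). Chlorophyll and carotenoid synthesis had 12 of 15, at 15.4 h, and 8, at 18.4 h (12 and 10 alone). Photosystem subunits had 21 of 28 in Norin 8 and 7 in osgi (21 and 6 alone) and the Calvin cycle 14 of 20 and 7 (14 and 7 alone). Protochlorophyllide reductase A (Os04g0678700) peaked at 14.6 h in Norin 8 and 19.5 h in osgi, with peak-to-trough differences of 7.50 and 4.24. A difference in these counts between the genotypes was not itself tested.

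Some genes had ratios that differed in size between sets. The Clp ATPase Os12g0230100 had a mean log2 ratio of 5.04 ± 3.52 (SD over arrays) in May 19, 7.97 ± 0.54 in June 19 and -0.02 ± 0.18 in July 16 plants, 7.99 ± 0.40 on Aug 10 to 12, 7.69 ± 0.47 on Aug 31 and 8.04 ± 0.35 on Oct 8. On Oct 9 its 4 arrays stood at 7.88, -0.13, 7.91 and 7.82. Os06g0170500 stood at 6.07 in May 19 plants and was well above background in neither genotype in July 16 plants. Os10g0371600 stood at -6.52 and -0.50 (a change of 6.02 ± 0.26) and Os09g0467700 at 0.31 and 4.67 (a change of 4.36 ± 0.23). Os12g0628500, Os12g0628100 and Os12g0609500 are genes of chromosome 12. In July 16 plants the first stood at -5.07 ± 0.65 and the second at -4.68 ± 0.89, and the third was at least 13.3-fold lower in osgi. On Oct 8 they were at -0.59 ± 0.49, -0.51 ± 0.43 and 0.22 ± 0.59, and on Oct 9 at -4.38 ± 2.96, -4.63 ± 2.19 and -3.46 ± 2.48, with 0.06, -1.44 and 0.13 in replicate 3.

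Other splits of the samples were run for the counts of called genes given here, 100 for most comparisons, the real one included. They were not run for the comparisons of single times of day in June 19 plants, so chance was not examined that way there. Genes with a missing value were left out, so some real counts lie just under those reported. For osgi against Norin 8, where signs of time point means were flipped, 1 of 100 gave as many genes as the real 2256, 2083, 1793 and 1805 (May 19, June 19, July 16, mean of 3; highest others 542, 133, 411 and 245), and so for 1599 on Aug 10 to 12 (1028) and 2782 on Oct 8 to 9 (1040). Reordered time points gave 1 of 100 for the rhythms in Norin 8 (12572, 12607 and 13306; highest others 40, 543 and 2876) and osgi (8632, 7982 and 10592; 18, 16 and 3700). They gave 1 of 100 also for the time-of-day ratio (6636, 6285 and 7164; 711, 763 and 719, and 2561 on Aug 10 to 12; 259). Regrouped transplantings gave 1 of 100 for July 16 against May 19 in Norin 8 (3162; 287) and osgi (4747; 1). For June 19 against May 19 they gave 3 of 100 in Norin 8 (669; highest other 1358) and in osgi (959; 3313), and the highest in osgi is several times the real count. In both genotypes the splits other than the real one that called as many were the same pair, which put July 16 plants in one group at 9 or 10 time points and in the other at 1 (differences of 8 and 9, against a median of 2 over 99 splits). They point to a structure of the samples by transplanting. For Norin 8 between the October days 1 of 35 splits gave as many (3955; highest other 1), on days that are also slides. For June 19 against May 19 the 3 of 100 lay under the share set beforehand for chance. The pair of splits that gave more genes mixed in July 16 plants, so these splits are no clean test of chance for that contrast. For the other counts with splits no other split gave as many, which argues against chance. Sign flips and reordered time points take time points as exchangeable, so they do not bear on a drift or on scan day.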
